A study of Drosophila melanogaster with 6 samples.

How the data were processed

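Total RNA of embryos aged 1 to 2 h was profiled on Affymetrix Drosophila Genome 2 arrays, with 3 arrays for embryos of zld germ-line clone mothers and 3 for yw embryos. Per the labels' protocols, RNA was extracted with TRIzol, turned into cDNA with a one-cycle kit and labelled with biotin, and the scans were processed and normalized with the Affymetrix GeneChip Operating Software (GCOS), whose version is not given in the sources used here. The deposited values are array intensity signals on a linear scale, 1 per probe set and array, with no detection calls. From the values, the mean of each array after leaving out the lowest and highest 2% was 149.9 on all 6 arrays, so the authors' signals carry a global scaling to a common level; the scaling target is not stated in the labels. Scanner files were not analysed here. The protocol field of the samples speaks of duplicate collections while the series text speaks of 3 replicate collections and biological replicates. The 3 arrays of a group were treated as replicates, and if some of them share a collection the p-values cover only the spread between such samples.

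Probe sets were named from the platform annotation, with symbols updated through gene identifiers to the RefSeq gene table of assembly GCF_000001215.4. Of the 18769 probe sets tested, 13646 had exactly 1 gene symbol, 402 had several and 4721 were unnamed here; 13543 of the 13646 were found in the RefSeq table. Probe sets with several genes or none were tested but not named. Where a gene had more than 1 probe set, the brightest over all 6 arrays stood for it. The 183 control probe sets were left out of the test.

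Signals were used as scaled by the authors. The test was limma (version 3.58.1, R 4.3.3; lmFit and eBayes with a trend) on log2(signal + 16), with the mutant and wild-type groups as the only term, all 6 arrays and Benjamini-Hochberg adjustment over all tested probe sets, called at an adjusted p under 0.05. The pseudocount of 16 damps noise at low signals, so fold changes are on the log2(signal + 16) scale and understate the change of dim transcripts. Every fold change is mutant over wild type. The methods' t-test was run as an alternative, since 3 arrays per group give a poor estimate of the spread of a single probe set.

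Gene lists were written before the data were examined, as were the test, the alternatives and the rule for naming genes. There were 23 lists with 287 entries, of which 227 had a named probe set. They were drawn from general knowledge of early fly development, not from a published table of these arrays, but some early zygotic genes may have been known as zelda-dependent, so their direction is not independent evidence. Camera with a preset correlation of 0.01 tested each list against all other genes, and it was repeated with an estimated correlation. Fry tested whether a list's genes move on balance in 1 direction or in either. Adjustment was over the 23 lists. Named genes were zld, the 8 largest falls and 8 largest rises among called probe sets with separate groups, a brighter mean above 19.0 (the median of probe set means) and exactly 1 gene, then up to 4 called members of each list or, where none was called, the member with the largest difference, and the stock markers. Other genes named in the text, among them trbl, CG13427, Nin, CG4440, tld, dpp, dpn, Sxl, hb, Kr, twi, bcd, exu, aub, grim and those of the closing observations, were chosen after their values were seen.

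Alternatives were pseudocounts of 1 and 64, a filter that left out probe sets below the median mean signal, quantile normalization, median centring, eBayes without trend, the methods' t-test, the replicate number as a block, array weights, probe sets with the suffixes _s_at and _x_at left out, each array left out in turn, estimated correlations and the mean of all probe sets of a gene. Leaving out wild-type replicates 1 and 2 together was added after the data were seen; the remaining wild-type array was then assumed to vary like the mutant ones. The test was checked on simulated arrays of 18769 probe sets in which 200 were changed. It recovered 74% of the 2-fold and 99% of the 4-fold changes, and 7.49% of its calls were unchanged probe sets. The changed probe sets were drawn from those with a mean signal above the median, so recovery among dim ones was not checked. Camera called the shifted list and 0 of 20 unchanged lists. The simulated noise was independent between probe sets, so this does not check camera on lists of correlated genes. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision of every value, and no genome positions were used beyond the order of neighbouring genes.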

Results

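Gene expression was measured in embryos of the fruit fly Drosophila melanogaster on 6 Affymetrix Drosophila Genome 2 arrays, 1 per RNA sample. The mutant group held 3 samples of embryos laid by mothers whose germ line carried a zelda (zld) mutation, so that the eggs lacked normal maternal zld function, and the wild-type group held 3 samples of yw embryos. All collections were of embryos aged 1 to 2 h, and per the series text 90% of a stained portion lay in nuclear cycles 8 to 13. Zelda is a zinc finger transcription factor loaded into the egg. The comparison asked which transcripts differed between embryos with and without its normal maternal function, at the passage from maternal to zygotic control. Each array gave 18952 signals, of which 183 belonged to control probe sets, leaving 18769 for the test. The median signal was 18.3, 17.7 and 16.4 on the mutant arrays of replicates 1, 2 and 3, and 20.3, 23.3 and 20.4 on the wild-type arrays. Between 5896 and 6016 probe sets per array had a signal above 100. Signals of 21 Bacillus control probe sets, whose targets a fly does not make, had a median of 4.8 and a 95th percentile of 18.9 over 126 values, so that signals under about this level cannot be told from background. Across probe sets, which are not independent replicates, the log2 signals of arrays of the same group correlated at 0.982 to 0.992, and those of different groups at 0.971 to 0.982. The number of arrays, 3 per group, limits the precision of every value.

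The targeted gene came first. The zld transcript had a signal of 225 ± 34.7 (SD, n = 3 arrays) in mutant embryos and 1017 ± 48.1 (SD, n = 3) in wild-type embryos. This was a log2 fold change of -2.11 (SE 0.114, adjusted p = 1.92e-04, limma), with all 3 mutant arrays below all 3 wild-type arrays. The labels do not describe the lesion, so this level bears on the labels only if the mutation removes RNA. The stock marker yellow (y) had signals of 4.47 ± 1.44 in mutant and 3.33 ± 0.306 in wild-type embryos (SD, n = 3 each), within background in both groups, with no difference past the threshold (log2 fold change 0.08, adjusted p = 0.642, limma). The white gene (w) was not named by any probe set here.

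The 8 largest falls under the naming rule were those of bard, CG8960, CG34214, CG14915, Bro, scw, Z600 and Elba3, with log2 fold changes from -4.50 to -3.61. The signal of bard was 560 ± 202 in wild-type and 8.57 ± 3.62 in mutant embryos (SD, n = 3 each). Brother (Bro), a partner of Runt-family transcription factors, had 325 ± 112 in wild-type and 3.07 ± 0.611 in mutant embryos. For 7 of these 8 genes, all but Elba3, the mutant mean was under 18.9, the background level, so these folds depend on the pseudocount. The largest rise was that of narya, which encodes a meiotic RING finger protein, from 1.77 ± 0.814 to 443 ± 30.8 (log2 fold change 4.69, SE 0.133, adjusted p = 7.49e-06, limma). Sickle (skl), an activator of apoptosis, rose from 16 ± 6.71 to 178 ± 14 (log2 fold change 2.62, SE 0.189, adjusted p = 5.37e-04). CG13937, pst, Mrp5, CG8323, Jhbp5 and CG3397 had log2 fold changes from 1.99 to 2.34. For narya, skl, CG13937, Mrp5 and CG3397 the wild-type mean was under 18.9, so their folds and order depend on the pseudocount: with a pseudocount of 1, CG13937, CG3397 and Mrp5 were at 3.97, 3.60 and 3.52, above skl at 3.47. The calls of CG13937, CG8323 and CG3397 ended without mutant replicate 2 or 3, and that of Mrp5 without mutant replicate 3.

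Over all 18769 probe sets, 146 were lower and 162 higher in mutant embryos at an adjusted p under 0.05 (limma). Of these, 88 were lower and 86 higher by at least 2-fold. The 146 lower probe sets held 127 with exactly 1 gene, naming 127 genes, 5 with several genes and 14 unnamed here. The 162 higher probe sets held 126 with exactly 1 gene, naming 126 genes, 10 with several and 26 unnamed here. Orai was counted in both directions, with a probe set at -1.53 (adjusted p = 0.0398, limma) and another at 1.75 (adjusted p = 0.0064, limma). At an unadjusted p under 0.05 there were 1628 lower and 1256 higher probe sets. The 3 mutant arrays lay all below or all above the 3 wild-type arrays for 21.8% of probe sets (13.6% below and 8.11% above), where chance gives 10%. The median log2 fold change over all probe sets was -0.05. The methods' t-test, run on the same log2 values, gave 0 lower and 2 higher probe sets after Benjamini-Hochberg adjustment, and 1485 lower and 1006 higher at an unadjusted p under 0.05. Leaving out mutant replicate 1, 2 or 3 gave 66, 56 or 45 lower and 69, 46 or 35 higher probe sets; without wild-type replicate 2 there were 90 lower, and without wild-type replicate 3 there were 156 lower by at least 2-fold. With median centring of the arrays, which moved the median log2 fold change by 0.157, the split was 127 lower and 552 higher, a higher share of 81.3% against 52.6%.

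**Figure D1:**
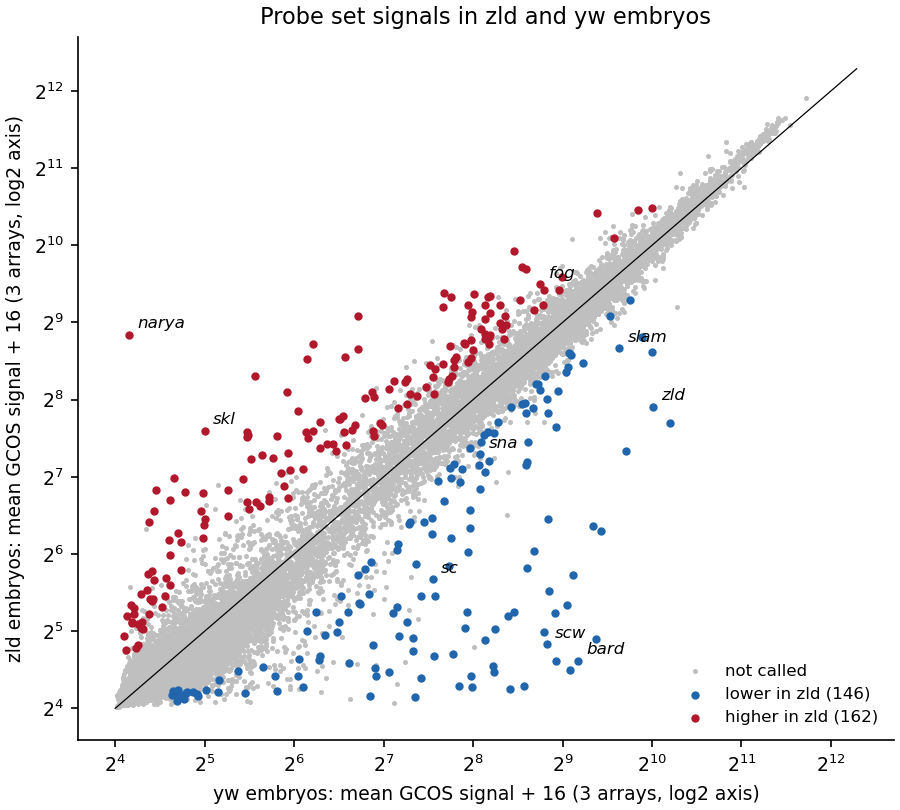
Mean GCOS signal plus 16 of each of the 18769 tested probe sets in yw embryos (horizontal, log2 axis) and in embryos of zld mutant mothers (vertical, log2 axis), 3 arrays per group, with the diagonal marking equal means. The 146 probe sets lower in mutant embryos are blue, the 162 higher ones red, and narya stands apart at the upper left.

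Genes of cellularization and of the blastoderm cell cycle fell together. Of the 7 measured members, 6 fell and 0 rose, and 7 fell when adjusted over the list alone. Halo, which acts in lipid droplet transport, fell from 539 ± 162 to 37.1 ± 5.46 (SD, n = 3 each; log2 fold change -3.35, SE 0.211, adjusted p = 2.60e-04, limma). The mitotic inhibitor Z600 fell from 427 ± 159 to 15.7 ± 1.04. Sry-alpha and nullo, which act on the actin network of the forming cells, fell by 2.61 and 2.77 on the log2 scale. The member not called was trbl, a regulator of mitosis (log2 fold change -0.67, adjusted p = 0.0543). The median log2 fold change of these genes was -2.61 (camera, adjusted p = 2.53e-12 with the preset correlation; adjusted p = 0.224 with an estimated correlation; fry, adjusted p = 0.00334).

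Other early zygotic genes of the blastoderm, most of them known by annotation number only, showed the same direction. Of 19 measured genes, 16 fell and 0 rose, and 18 fell when adjusted over the list alone. CG13713 went from 265 ± 58.3 to 13.7 ± 3.13 and CG18269 from 235 ± 52.2 to 5.4 ± 4.78 (SD, n = 3 each). Elba3, a subunit of an insulator complex, went from 467 ± 192 to 21.7 ± 3.48. CG13427, Nin and CG4440, the 3 that did not pass, had log2 fold changes of -1.03, -0.29 and -0.16 and mutant signals of 574, 734 and 902. The list's median log2 fold change was -2.80 (camera, adjusted p = 1.74e-25; adjusted p = 0.224 with an estimated correlation; fry, adjusted p = 0.00334). As given further on, no muscle or matrix gene passed singly, but some, such as Mlc1 and vkg, had higher signals on wild-type replicates 1 and 2 than on the other arrays. Without these arrays, an alternative chosen after seeing the data, 10 of the 19 early genes and 4 of the 7 cellularization genes were called lower, and the list medians were -2.72 and -2.17.

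In the dorsal ectoderm and amnioserosa list, scw and tsg had the largest falls. Of 16 measured genes, 6 fell and 0 rose, and 12 fell when adjusted over the list alone. Screw (scw), a BMP ligand, fell from 437 ± 119 to 12.6 ± 0.757 (SD, n = 3 each; log2 fold change -3.96, SE 0.183, adjusted p = 1.85e-04, limma). The extracellular BMP regulator tsg fell from 147 ± 64.1 to 1.70 ± 0.854, and the homeobox genes zen and zen2 fell by 1.63 and 2.36 on the log2 scale. The protease gene tld and the ligand gene dpp also passed, at -1.78 and -1.38, dpp with an adjusted p of 0.0483. Over the whole list the median was -0.96 (camera, adjusted p = 4.99e-09; adjusted p = 0.412 with an estimated correlation; fry, adjusted p = 0.0156). Without wild-type replicates 1 and 2 together, 3 members were called and the median was -0.66, and the calls of zen and zen2 ended at -1.46 and -2.33; zen2 was also not called without mutant replicate 3.

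Among proneural and neuroblast genes, 4 of 9 fell and 0 rose, and 5 fell when adjusted over the list alone. The 4 were ac, sc and l(1)sc, neighbouring proneural genes of the achaete-scute complex, and esg, a snail-family factor. Their log2 fold changes were -2.03, -1.87, -1.94 and -1.87. The signal of sc fell from 171 ± 20 to 35.1 ± 4.31 (SD, n = 3 each; SE 0.144, adjusted p = 7.14e-04, limma). The list's median was -1.22 (camera, adjusted p = 9.22e-07; adjusted p = 0.337 with an estimated correlation; fry, adjusted p = 0.00948). Without wild-type replicates 1 and 2, 1 member was called and the median was -0.65. Signals of sex determination overlap with this list through sc and dpn. Of their 4 measured genes, sc alone fell, and 3 fell and 1 rose when adjusted over the list alone. The values of upd1 and dpn were -1.04 (adjusted p = 0.0598) and -1.22 (adjusted p = 0.0792). The brightest probe set of Sxl, the sex switch gene, was at 0.26 (adjusted p = 0.307), while another probe set of Sxl fell by 1.49 (adjusted p = 0.0268), so the probe sets of this gene disagreed. For these signals the median was -1.13 (camera, adjusted p = 0.023; adjusted p = 0.337 with an estimated correlation; fry, adjusted p = 0.00545). Without wild-type replicate 1 its camera adjusted p was 0.0622. In the dosage compensation list 0 of 5 genes passed, and 1 fell and 1 rose when adjusted over the list alone. Its median was 0.11 and its mean -0.04 (camera, adjusted p = 0.726), with msl-2 at -0.57 and overlapping arrays.

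**Figure D2:**
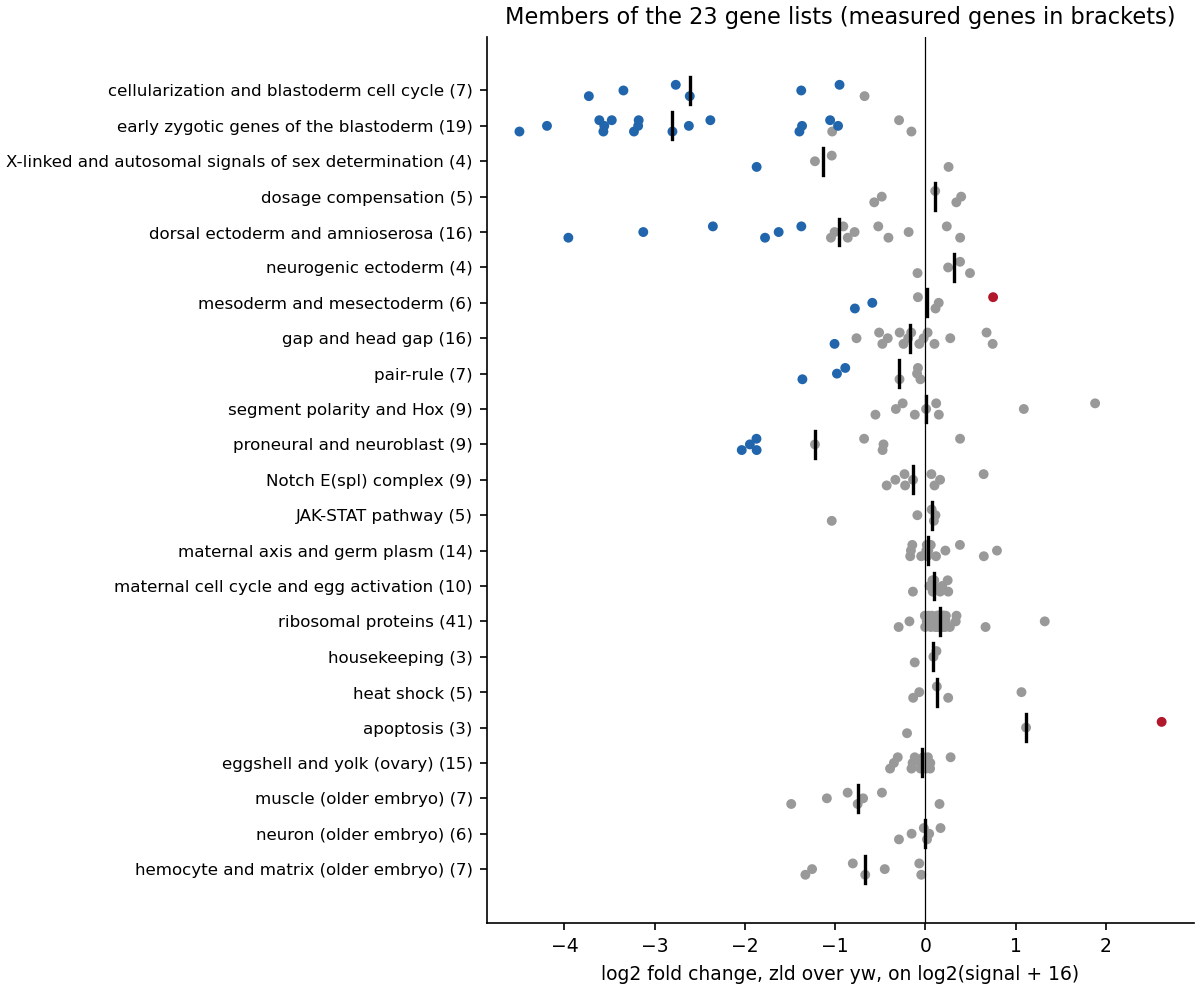
Log2 fold change on log2(signal + 16), mutant over wild type, of each measured member of the 23 gene lists (horizontal), with 1 line per list and the number of measured genes in brackets. Blue points are genes called lower, red points genes called higher and grey points genes not called; black bars are list medians, which reach -2.80 in the early zygotic list.

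In the pair-rule list 3 of 7 genes fell and 0 rose, and 3 fell when adjusted over the list alone. These were eve, ftz and hry, with log2 fold changes of -0.89, -0.98 and -1.36 (adjusted p = 0.0234, 0.0253 and 0.0313, limma). The signal of eve was 140 ± 21.5 in wild-type and 67.9 ± 5.89 in mutant embryos (SD, n = 3 each). For change in either direction the pair-rule list passed (fry, adjusted p = 0.00671). The pair-rule median was -0.29 (camera, adjusted p = 0.023; adjusted p = 0.593 with an estimated correlation; fry, adjusted p = 0.14). This call ended without wild-type replicate 1 (median -0.23), and the sign turned without wild-type replicate 2 (median 0.05) and without replicates 1 and 2 (median 0.27, 0 members called). In the gap and head gap list 1 of 16 genes fell, tll at -1.01 (adjusted p = 0.0471), and 1 fell and 1 rose when adjusted over the list alone. Hunchback (hb), which is also maternal, was at -0.02 and Kr at -0.42, neither called, and the list's median was -0.17 (camera, adjusted p = 0.778). In the segment polarity and Hox list 0 of 9 genes passed, and 2 rose when adjusted over the list alone. For change in either direction this list passed (fry, adjusted p = 0.0131). Its largest difference was that of mid, at 1.88 (adjusted p = 0.0598), and its median was 0.01 (camera, adjusted p = 0.486), or 0.18 and past the threshold without wild-type replicate 2 (adjusted p = 0.0406), and 0.12 and past it without replicates 1 and 2 (adjusted p = 0.0393).

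Mesoderm and mesectoderm genes went both ways. T48 and sna fell by 0.59 and 0.78 on the log2 scale, and fog rose from 415 ± 57.6 to 708 ± 78.7 (SD, n = 3 each; log2 fold change 0.75, SE 0.124, adjusted p = 0.0275, limma). T48 and fog act in apical constriction, and sna is the snail repressor. Twist (twi), its partner in the mesoderm, was at -0.08 and not called. Of the 6 measured genes 2 fell and 1 rose, over all probe sets and also when adjusted over the list alone. The list's median was 0.01 and its mean -0.07 (camera, adjusted p = 0.778), and it passed for change in either direction (fry, adjusted p = 9.21e-04). In the neurogenic ectoderm list 0 of 4 genes passed, and 1 rose when adjusted over the list alone, pyr at 0.49 (adjusted p = 0.0945 over all probe sets) with a signal under background in both groups. That list's median was 0.32 (camera, adjusted p = 0.0972), or 0.44 and past the threshold without wild-type replicates 1 and 2 (adjusted p = 0.0321). Among 9 genes of the Notch E(spl) complex 0 passed, also when adjusted over the list alone; E(spl)m7-HLH was at 0.64, and the median was -0.14 (camera, adjusted p = 0.939). Among 5 genes of the JAK-STAT pathway 0 passed, and 1 fell when adjusted over the list alone, the ligand gene upd1. The median of that list was 0.07 and its mean -0.17 (camera, adjusted p = 0.936), and it passed for change in either direction (fry, adjusted p = 0.00885). The calls of eve, ftz, hry, tll, T48, sna and fog ended when any 1 mutant array was left out, with the sign kept. They also ended without wild-type replicate 1 or 2 for ftz, hry, tll and sna, without replicate 1 or 3 for fog, without replicate 2 for eve and without replicate 3 for T48. Other settings that ended calls were median centring for T48 (-0.43), quantile normalization for tll, a pseudocount of 64 for tll and hry, and eBayes without trend for sna, fog, tll and hry.

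**Figure D3:**
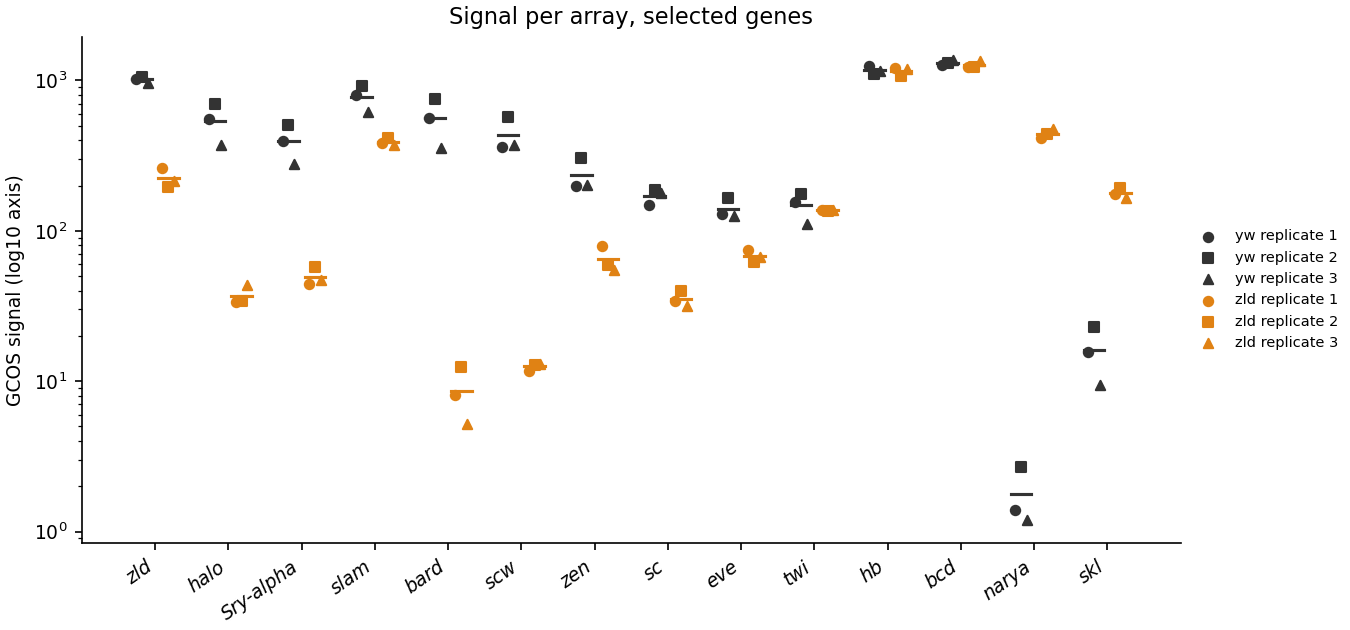
GCOS signal (log10 axis) of 14 genes on each of the 3 yw arrays (dark) and 3 arrays of embryos of zld mutant mothers (orange), with a bar at each group mean and the replicate shown by the marker shape. The 3 mutant signals of bard lie between 5.2 and 12.4 against 355 to 758 in yw, while hb and bcd overlap.

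Maternal transcripts as listed did not pass as single genes. Of 14 genes of the maternal axis and germ plasm 0 passed, and 3 rose when adjusted over the list alone, namely vas, exu and aub. Vasa (vas), a germ plasm helicase, was at 62.8 ± 3.07 in mutant and 29.5 ± 1.25 in wild-type embryos (SD, n = 3 each; log2 fold change 0.79, adjusted p = 0.06, limma). Bicoid (bcd), the anterior determinant, was at -0.05. The median of the list was 0.03 (camera, adjusted p = 0.123), and its sign turned under quantile normalization. For change in either direction this list passed (fry, adjusted p = 4.52e-04). Among 10 genes of the maternal cell cycle and egg activation 0 passed, also when adjusted over the list alone. Their largest difference was that of twe, at 0.25, and their median was 0.09 (camera, adjusted p = 0.0814). This list passed as higher without mutant replicate 1 (median 0.19, adjusted p = 0.0148) and without wild-type replicate 3 (median 0.20, adjusted p = 0.0179), and over all alternatives the adjusted p ran from 0.0148 to 0.824.

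Ribosomal protein genes were higher as a list, though 0 of 41 passed singly and 1, RpS10a, rose when adjusted over the list alone. Log2 fold changes of 37 of the 41 were above 0, with a median of 0.16 (camera, adjusted p = 2.53e-05; adjusted p = 0.593 with an estimated correlation; fry, adjusted p = 0.357). Under quantile normalization the median was 0.02 (camera, adjusted p = 0.108), and without wild-type replicates 1 and 2 it was -0.03. Leaving out 1 array gave medians of 0.0859 to 0.266, and the highest median over all alternatives was 0.314. The camera adjusted p ran from 6.51e-10 to 0.593 over the alternatives. RpS10a itself was at 1.32 (adjusted p = 0.0556, limma). Its signals were 54.6, 19.8 and 20 on mutant replicates 1, 2 and 3. All but the first were near background, and its wild-type signals were within background. Among 3 housekeeping genes 0 passed, also when adjusted over the list alone, with betaTub56D at 0.12 and a median of 0.09 (camera, adjusted p = 0.778), both at -0.03 under quantile normalization. Of 5 heat shock genes 0 passed, and 1 rose when adjusted over the list alone, Hsp68 at 1.06 (adjusted p = 0.147), with a list median of 0.13 (camera, adjusted p = 0.362) that quantile normalization took to -0.01; the list passed as higher with suffixed probe sets left out (median 0.25, adjusted p = 0.0476). Of 3 apoptosis genes 1 rose, skl, and 2 rose when adjusted over the list alone. The other was grim at 1.12 (adjusted p = 0.0905 over all probe sets, limma). Signals of grim were 50.6, 20.6 and 22.8 on mutant replicates 1, 2 and 3. All but the first were near background, and its wild-type signals were within background. The median of these 3 genes was 1.12 (camera, adjusted p = 0.0235; adjusted p = 0.337 with an estimated correlation; fry, adjusted p = 0.00364), and the call ended without wild-type replicate 1 (adjusted p = 0.0622) and with dim probe sets left out (median 1.21, adjusted p = 0.295). Their median was 2.47 with a pseudocount of 1 and 0.449 with 64, and the adjusted p ran from 0.0159 to 0.337 over the alternatives.

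Some markers of tissues of older embryos had higher signals on wild-type replicates 1 and 2, though no muscle, matrix or neuron gene passed singly. Others did not, such as Hml, at 4.6, 7.5 and 7.3 on wild-type replicates 1, 2 and 3 against a mean of 5.9 in mutant embryos. Mlc1, a myosin light chain gene, had signals of 122, 149 and 34.1 on wild-type replicates 1, 2 and 3, against 21.4 ± 3.34 (SD, n = 3) in mutant embryos. The collagen gene vkg had 56.2, 83.4 and 10.6, against 6.90 ± 0.436. Of 7 muscle genes 0 passed, and 2 fell when adjusted over the list alone; of 7 hemocyte and matrix genes 0 passed, also when adjusted over the list alone. The list medians were -0.75 and -0.67 (camera, adjusted p = 0.0235 for each; adjusted p = 0.593 and 0.533 with an estimated correlation; fry, adjusted p = 0.357 and 0.227). Without wild-type replicate 2 the medians were -0.37 and -0.41 and neither list was called, and without wild-type replicates 1 and 2 they were -0.07 and -0.22. The muscle call also ended without wild-type replicate 1 and without mutant replicate 1 or 2, and the matrix call without mutant replicate 1. The muscle call ended as well with dim probe sets left out (median -0.59), with array weights (-0.66) and with suffixed probe sets left out (-0.92). Among 6 neuron genes 0 passed, also when adjusted over the list alone, with futsch at -0.29 and a median of 0.00 (camera, adjusted p = 0.891). Of 15 eggshell and yolk genes 0 passed, also when adjusted over the list alone, with Yp1 at -0.39 and a median of -0.04 (camera, adjusted p = 0.891). Without wild-type replicate 1, 6 lists passed. In all, 10 of the 23 lists passed with camera's preset correlation, 8 lower and 2 higher, and 0 with estimated correlations; fry called 6 in a direction and 11 for change in either direction.

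**Figure D4:**
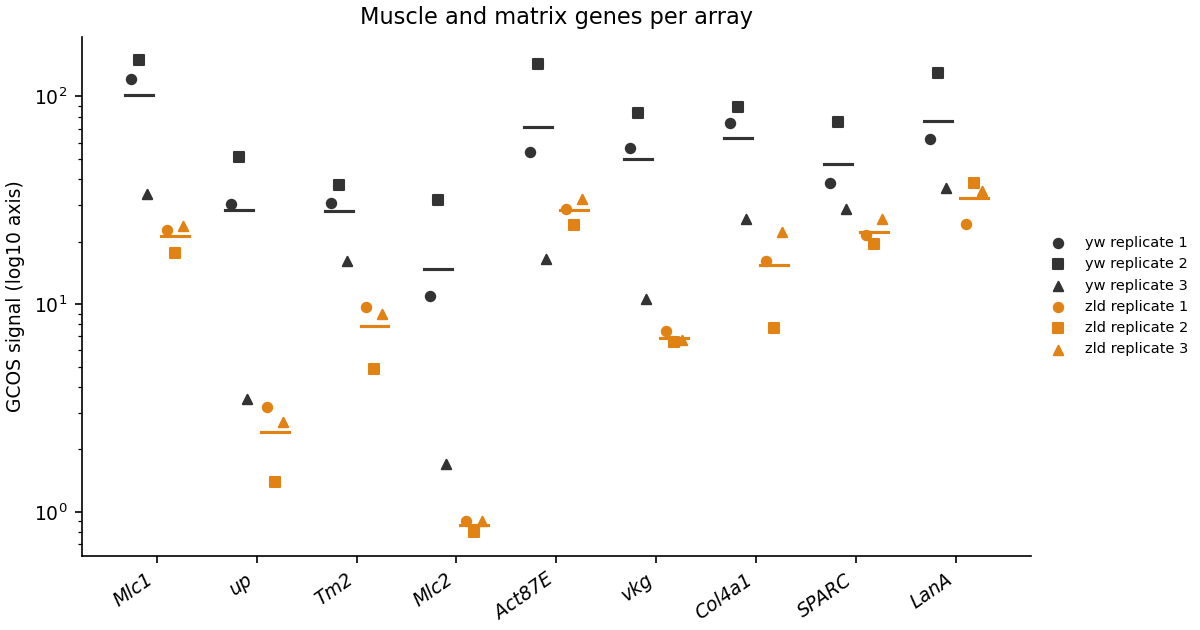
GCOS signal (log10 axis) of 9 muscle and matrix genes on each array, with yw arrays dark, arrays of embryos of zld mutant mothers orange, a bar at each group mean and the replicate shown by the marker shape. Mlc1 reads 122 and 149 on yw replicates 1 and 2 but 34.1 on yw replicate 3.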

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

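The count of probe sets also called without mutant replicate 2 was chosen after the result was seen. The control probe set for the middle of the 18S ribosomal RNA had a signal of 75.4 on mutant replicate 2, above the highest wild-type signal of 24, and the ratio of the signals at the 3′ and 5′ ends of Act5C, an actin gene, was 5.16, above the highest wild-type ratio of 2.47. Control probe sets were left out of the 18769 tested; fitted apart with limma, 0 of 183 differed between the groups at an adjusted p under 0.05 and 9 at an unadjusted p under 0.05. The same ratio of eIF4a was 3.87 on that array, while that of Gapdh, 1.57, lay between the values of the other arrays.

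A candidate explanation is loss of 5′ RNA or weaker priming in mutant replicate 2, which could distort folds. Without that array, the median ratio of the log2 fold change to its full value was 1.001 over the 146 lower and 1.001 over the 162 higher probe sets. This ratio decides nothing, since the probe sets were called with that array included and an array far from the others would have ended their calls. Without it 54 of the 146 lower and 46 of the 162 higher probe sets were also called, so it does not account for all of the calls, and for the others this stays open. What raised the 18S signal stays open, and no biological explanation was tested.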

How the results depend on the processing

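Leaving out wild-type replicates 1 and 2 together was chosen after the data were seen; the other alternatives were fixed beforehand. All 146 lower and 162 higher probe sets kept their sign under each alternative that tested them. This was nearly certain in advance, since they were called on these same arrays. Of the 36 called genes named by rule, 24 stayed called in all 6 fits that left out 1 array, 21 without wild-type replicates 1 and 2, and 1, narya, under the methods' t-test. These genes were picked mainly for large folds or small p-values, so they do not stand for all calls. Without mutant replicate 3, 45 of the 146 lower and 34 of the 162 higher probe sets were also called. The zld transcript ran from -2.22 to -1.91 over the alternatives. With the suffixes left out it had no value, as its probe set carries one. Counts of calls and zld were similar in 67 cases, stronger in 6, weaker in 29 and reversed in 0. For single genes and lists these were 1167, 41, 178 and 41. Counts were graded by size. The 88 probe sets lower by at least 2-fold became 130 with a pseudocount of 1, graded as similar. With a pseudocount of 64 they became 50, graded as weaker. Where no reason is given below, the cause was not tested.

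A pseudocount of 1 gave 130 probe sets higher by at least 2-fold, and one of 64 gave 50 lower and 34 higher by at least 2-fold, since a larger pseudocount shrinks folds. Leaving out dim probe sets gave 264 lower and 327 higher; the number of tests and the fitted variance trend both changed there, and their parts were not tested. Median centring gave 552 higher and 176 higher by at least 2-fold; it moved the median log2 fold change by 0.157. The methods' t-test gave 0 lower and 2 higher, 0 and 2 of them by at least 2-fold, and left zld at -2.11 with an adjusted p of 0.0836 (range 1.68e-05 to 0.0836). Camera with estimated correlations called 0 lists.

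The replicate numbers do not pair the samples by the labels. With replicate number as a block there were 76 lower, 75 higher and 57 higher by at least 2-fold, and 74 lower and 72 higher probe sets were shared with the unblocked fit. With this block the calls of eve, ftz, hry, tll, T48 and sna ended, and the maternal cell cycle list passed.

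Leaving out 1 array gave 45 to 213 lower, 35 to 227 higher, 42 to 156 lower by at least 2-fold and 27 to 107 higher by at least 2-fold probe sets, and 6 to 11 lists. Without wild-type replicates 1 and 2 there were 43 lower, 51 higher, 39 lower by at least 2-fold and 45 higher by at least 2-fold; 38 lower and 37 higher were shared. Fewer arrays give less power, and the lone wild-type array was assumed to vary like the others.

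List medians and genes whose sign turned were mostly near 0. With a pseudocount of 64 the mesoderm list was at -0.0072 and the neuron list at 0.000896. With dim probe sets left out the neuron list was at 0.104. Quantile normalization gave betaTub56D -0.0265, the E(spl) list 0.0101, maternal axis -0.00295, housekeeping -0.0265, heat shock -0.00841, eggshell and yolk 0.0321 and neuron 0.099. Median centring gave E(spl) 0.0198, eggshell and yolk 0.115 and neuron 0.157. Without the suffixed probe sets mesoderm was at -0.0832, JAK-STAT at -0.01, housekeeping at -0.015 and neuron at 0.0171. Leaving out 1 array gave ranges of -0.202 to 0.136 for mesoderm, -0.121 to 0.0478 for neuron, -0.239 to 0.124 for E(spl), -0.0114 to 0.103 for maternal axis, -0.0301 to 0.1 for JAK-STAT, -0.151 to 0.178 for segment polarity and -0.681 to 0.0495 for pair-rule. Without wild-type replicates 1 and 2, msl-2 was at 0.427, betaTub56D at -0.119, gap at 0.196, pair-rule at 0.272, E(spl) at 0.237, JAK-STAT at -0.0239, maternal axis at -0.0783, maternal cell cycle at -0.0453, ribosomal proteins at -0.0345, housekeeping at -0.1 and heat shock at -0.000155.

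Signal over background limits the dim end: 95% of the Bacillus control signals were at or below 18.9, close to the median of probe set means, 19.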

Other observations

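Tests on the age of the collections were chosen after the results were seen, and for the other probe sets of called genes the statistic was changed to medians per gene, with a calibration on lower genes, after a first result led by mod(mdg4). The genes in this paragraph and the next were picked from the called genes after their values were seen and stand for no tested group. Dad, an inhibitor of BMP signalling, fell from 148 to 42.3 (log2 fold change -1.49, adjusted p = 0.0148), the proneural gene ato from 98.1 to 28.5 (-1.35, adjusted p = 0.0131) and Brd, of the Bearded family of Notch regulators, from 273 to 132 (-0.94, adjusted p = 0.0296). The log2 fold change of spo, an enzyme of ecdysone synthesis, was -1.97 and that of Osi6 was -3.41. Osi6 had signals of 212, 561 and 83.5 on wild-type replicates 1, 2 and 3 and kept a share of 0.203 of its excess on the linear scale on replicate 3.

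The gene rhi, for a chromatin protein of the piRNA pathway, rose from 225 to 406 (0.81, adjusted p = 0.00603), tut, a germ-line RNA-binding protein, from 55 to 165 (1.36, adjusted p = 0.00434) and CycJ, a cyclin, from 103 to 245 (1.16, adjusted p = 0.0178). The log2 fold change of pon, a partner of the cell-fate factor Numb, was 1.85.

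Genes lower in mutant embryos lay near each other. Of 124 placed genes, 32 had another lower gene among the 5 genes on either side, against a mean of 10.7 and a 95th percentile of 18 in 10000 random draws (permutation of genes, one-sided p = 1e-04, the smallest these draws can give). Among them were ac, sc and l(1)sc, then zen2, zen and ftz, and CG13716, CG34266, CG15876, CG13713, CG13712 and CG13711. As a hypothesis, early genes activated with zelda may lie in clusters; probes shared by related neighbours were not examined, and the fixed lists held many of these genes.

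A first pattern to weigh is the fall of early genes beside higher signals of some muscle and matrix markers on wild-type replicates 1 and 2. These signals may reflect older embryos there. Of the excess over mutant arrays, the early zygotic and cellularization genes kept a share of 0.572 on wild-type replicate 3 (95% jackknife interval over genes 0.422 to 0.721, 26 genes). The markers kept 0.0187 (-0.109 to 0.146, 14 genes). Both shares rest on 1 wild-type array. The intervals cover the spread between genes, which are not independent, and not that between arrays. On that array, older embryos that carry these markers do not account for all of the fall. A smaller age difference between that array and the mutant ones was not tested. Of the 146 lower probe sets 1, unnamed here, lay at or below the upper bound of the markers. Single markers such as Tm2 (0.317), Pxn (3.47) and Hml (9.33) lie beyond that bound, and the lowest was bt (-2.22). The excesses of bt, Pxn and Hml were small, at 8.17, 3.95 and 0.15. A loss on 1 array also works against a call, so for single probe sets older embryos stay open. The prediction was that younger mutant embryos would lower later genes at least as much. The median of 23 gap and pair-rule genes lay 2.5 above that of the 26 early genes (-0.19 against -2.69). By permutation of genes p was 1e-04, the smallest these draws can give. This cannot decide on age. The later genes include hb, which is also maternal (1156 in mutant and 1173 in wild-type embryos). They also include cad, brighter still (1572 in mutant and 1558 in wild-type embryos), and slp2, within background in both groups. The onset of the early and later lists was not timed here, so younger mutant embryos stay open. The genetic background and the germ-line clone procedure differ with the group, and these cannot be told apart from zelda by the design.

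A second pattern is the set of genes higher in mutant embryos. Younger age that keeps maternal transcripts in general high is a candidate explanation. The 24 listed maternal genes had a median of 0.0795 (upper quartile 0.195), below 0.512, which is 50% of the median of the higher probe sets. A rise of that size, relative to the scaled signals, was thus not seen in these genes. Each array carries a scaling to a common mean, however. These genes are mostly bright, with list medians of 1010 and 1030 in wild-type embryos. Such scaling could remove a general rise, so this median cannot decide on one. The bar also comes from probe sets picked for their rise, so younger age stays open. The largest maternal cell cycle and egg activation list shift over the alternatives was 0.249, with median centring. Maternal transcripts cleared early were not listed apart. Linked blocks of another background could place higher genes side by side. Of 124 placed genes, 10 had a higher neighbour, against a mean of 10.8 and a 95th percentile of 18 in random draws (permutation of genes, one-sided p = 0.63). This count bears only on close neighbours. A difference of background at scattered genes would not show in it, so background stays open. Sequence variants under single probe sets stay open. Other probe sets of 12 higher genes had a median of -0.0891 against 0.812, with the sign kept in 2 of 12. Those of 10 lower genes read -0.23 against -1.44, with the sign kept in 8 of 10. With the changed statistic, the higher genes met the criterion set beforehand for sequence variants, a median far below the called one. The lower genes met it too, so this criterion cannot decide. Orai was in both groups of genes, as its probe sets were called in opposite directions. Slower clearance of maternal RNA without normal maternal zelda function was not tested.

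The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the only 1 of the 10 to reach 146 lower and 162 higher probe sets, and the only 1 to reach 88 lower and 86 higher by at least 2-fold; the highest other split gave 0 for each. For lists, 3 of the 10 splits reached 10 or more, with 10 in the real one and 11 as the highest other. Both splits with 11 put wild-type replicates 1 and 2 on the same side, which points to a structure of the samples besides their group.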
